A study of Homo sapiens with 6 samples.

How the data were processed

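RNA sequencing was done on total RNA of 5637 cells, an established human bladder carcinoma line. Per the labels' protocols, RNA was taken from transfected cells with TRIzol and made into libraries with the VAHTS Universal V6 kit. The labels give 3 libraries named NC and 3 libraries of cells with a short hairpin RNA against RAD51C (sh-RAD51C). They do not say what NC stands for, which hairpin sequence was used, or whether the 3 libraries of a group came from separate cultures. P-values therefore measure the spread between these libraries, which may be technical.

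The deposited values are FPKM (reads or fragments scaled by gene length and by the library's total) for 23024 gene symbols, calculated by the authors. Per the submitters' processing notes, the build was hg38, and R 3.2.0 and DESeq2 were named without a role. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. All 6 columns were matched to libraries by the titles, and 0 further per-sample columns were left unused. Because strand use is not stated, values of overlapping genes and of antisense genes are uncertain, as are values of near-identical paralogs.

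FPKM values are not counts, but each was a whole multiple of a step set by the gene's length and the library's total, so whole reads per gene could be inferred. The total behind each library came from 488 genes whose genomic length in the RefSeq table gave the same whole number for NC 1. Inferred gene lengths were whole within 0.001 bases for 100.0% of the 11152 genes analysed, with RefSeq lengths used for 2 mitochondrial genes. The inferred totals were 36068282, 37546386 and 37560184 reads for NC 1, 2 and 3, and 38079825, 37104318 and 38003657 reads for sh-RAD51C 1, 2 and 3. On simulated libraries these steps returned all 6 counts for 99.0% of 11160 genes. The exact length of each simulated gene was supplied there, so finding the total from RefSeq lengths was not tested. Inferred reads served to describe depth and to run an added alternative, and the main tests used FPKM. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 3.51 to 11.64 over pairs), so none was treated as a repeat deposit.

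Genes with a mean of at least 1 FPKM over the 6 libraries were kept. Values were transformed as log2(FPKM + 1), and sh-RAD51C was compared with NC in limma 3.58.1 (R 4.3.3) with an empirical Bayes trend, no covariate and Benjamini-Hochberg adjustment over the genes kept. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and folds of mean FPKM are given beside them. The FPKM of RAD51C was also compared with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 libraries against 3.

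The choice of 35 gene lists, of the test and of the alternatives was made before the data were examined. List symbols were matched directly or, for 14 of 1104 matched entries, through an older symbol or synonym. Lists with at least 5 members among the genes kept, 32 in number, were tested with camera in limma at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry were alternatives. The genes named are RAD51C, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM, and up to 4 members per list with the smallest p. Other genes are named as chosen after their values were seen. Positions are those of GENCODE release 29 on GRCh38, the assembly also called hg38, taken from the reference used here because the deposited values carry no coordinates. GC content came from the longest GENCODE transcript and was found for 95.8% of the genes kept.

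The fit was tested on simulated libraries of 11160 genes, with reads drawn around the real means. All simulated genes had 1 common spread, and few were changed, against 49.4% called in the data. It recovered 14% of 50 genes changed by 1.1-fold, 68% of 50 changed by 1.2-fold, and all of those changed by 1.5-fold or 2-fold, and called 12 of 10932 unchanged genes. Camera called 0 of 30 unchanged simulated lists and called the 1 list that had been shifted by 0.3 (log2), also with an estimated correlation (adjusted p = 0.00119); simulated genes varied independently of each other. Alternatives covered the pseudocount, the filter, 4 rescalings, the variance model, a replicate block, 2 other thresholds, 2 other list tests and the omission of each library. A further 3 alternatives were chosen after seeing the data: limma's voom on the inferred reads, removal of each library's trend with gene length and GC content, and omission of genes whose exons overlap another gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the other calculations.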

Results

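Gene expression was measured in 6 libraries of 5637 cells, 3 named NC and 3 with a short hairpin RNA against RAD51C. The series asked how lowering RAD51C, proposed there as a hub gene in bladder cancer, alters expression in this line. Inferred depth was alike in the groups, 36068282 to 37560184 reads per NC library and 37104318 to 38079825 reads per sh-RAD51C library. Of the 23024 genes listed, 11152 had a mean of at least 1 FPKM and were tested.

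RAD51C, which acts in DNA repair by homologous recombination, was lower in every sh-RAD51C library than in any NC library. Its level was 13.8 ± 0.804 FPKM (SD, n = 3) in NC and 3.18 ± 0.288 FPKM (SD, n = 3) in sh-RAD51C, which is 23% of the NC mean. Single libraries held 14.7, 13.2 and 13.6 FPKM (2019, 1881 and 1937 inferred reads) in NC 1, 2 and 3. The sh-RAD51C libraries 1, 2 and 3 held 3.51, 3.09 and 2.95 FPKM (508, 436 and 427 inferred reads). The gene (ENSG00000108384.14) lies on chromosome 17 from 58692573 to 58735611, on the plus strand. Its log2 fold change was -1.83 ± 0.064 (SE; limma, Benjamini-Hochberg adjusted p = 7.16e-09), and the exact two-sided permutation test gave p = 0.1, the smallest it allows with 3 libraries per group.

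**Figure D1:**
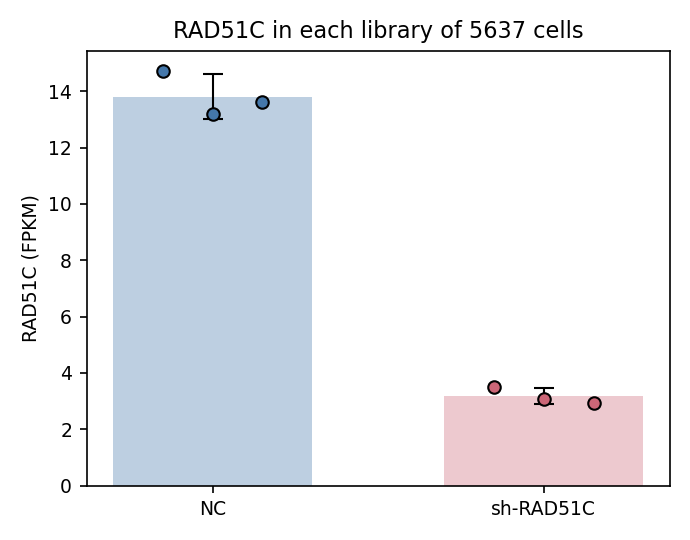
RAD51C in FPKM for each group. Bars show the mean of 3 libraries, error bars the SD and points the single libraries. The NC libraries lie between 13.2 and 14.7 FPKM and the sh-RAD51C libraries between 2.95 and 3.51 FPKM.

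The partners of RAD51C in homologous recombination did not move together. Of 33 measured members of that list, 9 were higher, 4 were lower and 20 were not called, and the list was not called (limma's camera, adjusted p = 0.687). RMI2, a subunit of the BLM helicase complex, fell from 9.2 ± 0.552 to 5.76 ± 0.267 FPKM, and the end-resection factor RBBP8 fell from 15.8 ± 0.124 to 12.7 ± 0.542 FPKM (SD, n = 3 each). SWI5 also fell, with a log2 fold change of -0.27, and NBN of the MRE11 complex rose by 0.19. Among genes chosen after their values were seen, XRCC3 rose by 0.21, while log2 fold changes of 0.15 for XRCC2 (limma adjusted p = 0.056) and 0.01 for RAD51D did not pass the test. XRCC2 passed in 6 of 20 alternatives, where its limma adjusted p ran from 0.0167 with quantile normalization to 0.186 without sh-RAD51C replicate 3, and was 0.0273 without sh-RAD51C replicate 1. Adjusted over the list alone, 7 members were higher and 4 lower.

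The Fanconi anaemia list had 3 higher and 4 lower members of 21 (camera adjusted p = 0.921), FANCL at -0.29 and FAAP100 at 0.26 among them. In the end joining list 2 of 18 members were higher and 2 lower (camera adjusted p = 0.648), with XRCC1 at -0.31 and POLM at 0.28. The p53 target list had 7 higher and 13 lower members of 29 and was not called (camera adjusted p = 0.145). Within it GADD45A, a stress-induced growth arrest gene, rose from 21.6 ± 0.598 to 46.5 ± 1.73 FPKM and PLK2 from 51.8 ± 1.53 to 104 ± 1.86 FPKM, while TP53INP1 and the repair gene DDB2 fell by 0.87 and 0.64 on the log2 scale. Adjusted over the list alone, the counts were the same for the Fanconi anaemia and end joining lists, and 7 higher and 14 lower for the p53 targets.

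Beyond the target, lists of YAP targets, ERK feedback genes and ribosome biogenesis genes were higher in the knockdown libraries, and basal and squamous markers and cholesterol synthesis genes were lower, by limma's camera at its preset correlation. With an estimated correlation none of these 5 lists was called (camera adjusted p from 0.173 to 0.257). The matricellular genes CCN1 and THBS1 rose 8.28-fold and 7.46-fold, and the water channel AQP3 and the elastase inhibitor PI3 were 9.32-fold and 7.56-fold lower, from 3 libraries per group. In all, 5511 of 11152 genes were called, 2589 higher and 2922 lower, with 174 of them changed by at least 1 on the log2(FPKM + 1) scale (63 higher and 111 lower), which counts fewer low genes than a fold of means would. The median called gene moved by 0.28 on that scale, against a median residual SD of 0.065 on the log2 scale. In 6513 genes (58.4%) the groups did not overlap, where chance gives 10% for 3 libraries against 3.

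CCN1, a secreted matrix protein and YAP target on chromosome 1 from 85580761 to 85583962, rose from 11 ± 1.31 to 90.9 ± 6.94 FPKM (SD, n = 3), a log2 fold change of 2.94 ± 0.075 (SE; limma adjusted p = 1.24e-09). THBS1, encoding thrombospondin 1, rose from 35.8 ± 3.88 to 267 ± 28 FPKM (log2 fold change 2.86 ± 0.08, limma adjusted p = 1.52e-09). The WNT inhibitor DKK1 rose from 4.98 ± 0.934 to 31.8 ± 1.76 FPKM. ANKRD1 rose from 0.512 ± 0.0589 to 7.33 ± 0.405 FPKM, 14.3-fold by means, and CCN2 rose 5.48-fold to 12.9 ± 0.687 FPKM. The cytokine receptor subunit IL7R rose 6.41-fold, and IL6, an inflammatory cytokine, rose from 0.735 ± 0.0389 to 6.29 ± 0.771 FPKM. CCND1, which encodes cyclin D1, rose 4.08-fold to 70.1 ± 2.54 FPKM. The transcription factor SOX9 rose 4.11-fold and the keratin gene KRT80 rose 3.94-fold. Across these 10 genes the largest limma adjusted p was 1.42e-08, for IL7R.

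AQP3, on chromosome 9 from 33441154 to 33447633, fell from 112 ± 8.13 to 12 ± 3.34 FPKM (SD, n = 3), a log2 fold change of -3.15 ± 0.149 (SE; limma adjusted p = 4.86e-08). PI3 fell from 95.9 ± 7.77 to 12.7 ± 3.86 FPKM, and the imprinted noncoding RNA H19 from 239 ± 26.5 to 33.5 ± 8.24 FPKM. The serpin genes SERPINB3 and SERPINB4 were 8.7-fold and 12.6-fold lower; they are close paralogs, so the split of reads between them is uncertain. FABP4, a fatty acid carrier, was 6-fold lower at 7.91 ± 2.2 FPKM. TNFSF10, which encodes the death ligand TRAIL, fell from 24.3 ± 0.931 to 4.46 ± 0.71 FPKM. The troponin gene TNNT3 was 5.93-fold lower, the complement gene CFB 5.2-fold lower and the basal keratin KRT14 5.53-fold lower. The largest limma adjusted p of these 10 genes was 2.42e-07, for CFB.

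**Figure D2:**
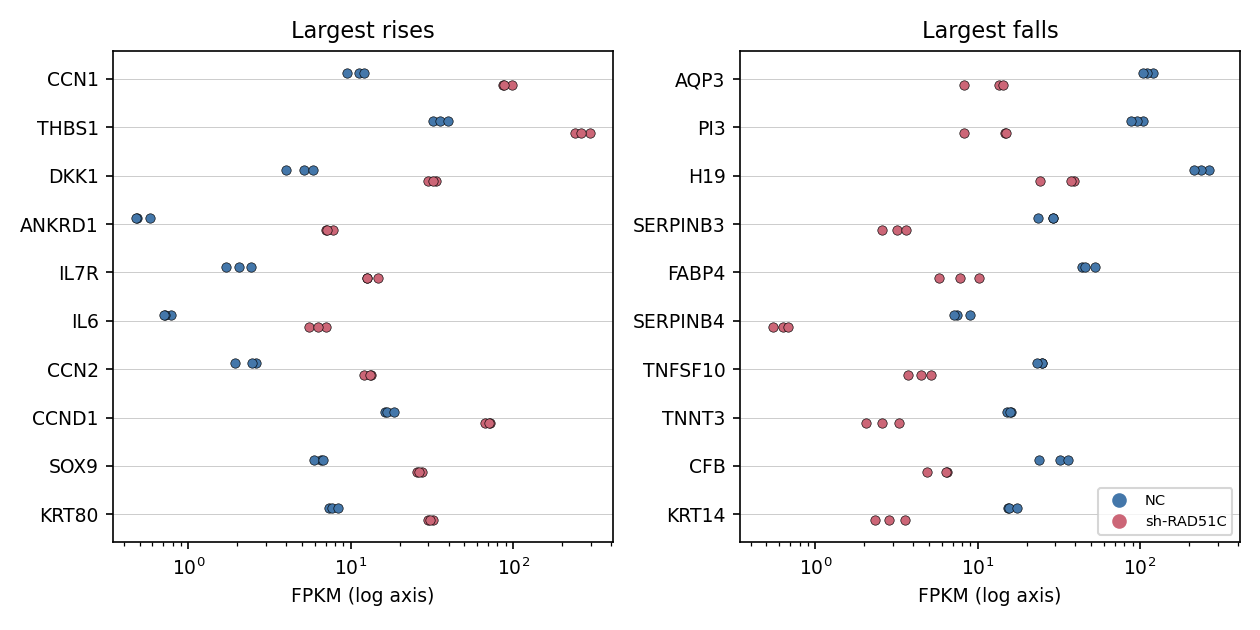
FPKM on a log axis in each library for the 10 genes with the largest rises and the 10 with the largest falls. Each point is 1 library, blue for NC and red for sh-RAD51C, and the groups do not overlap in any of these genes.

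**Figure D3:**
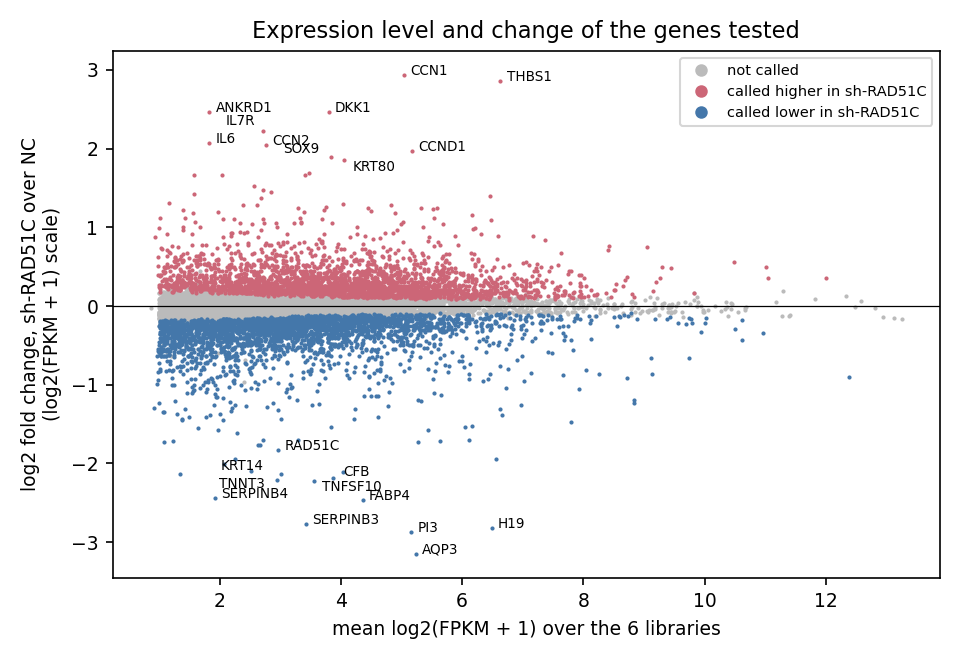
Log2 fold change of sh-RAD51C over NC against mean log2(FPKM + 1) for the 11152 genes tested. Points are genes, coloured by call, with 2589 called higher and 2922 called lower; RAD51C and the 20 genes with the largest changes are named.

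YAP target genes rose together. Of 22 measured, 19 were higher and 0 lower, with a median log2 fold change of 0.91 (camera adjusted p = 1.38e-11; adjusted p = 0.257 with an estimated correlation). Besides CCN1, ANKRD1 and CCN2, the list held FJX1, which rose from 7.71 ± 0.361 to 19.8 ± 0.443 FPKM. In the ERK feedback list, genes induced by growth factor signalling, 16 of 19 were higher and 0 lower (median 0.5, camera adjusted p = 2.51e-09; adjusted p = 0.19 with an estimated correlation). EPHA2, a receptor kinase, rose from 30.2 ± 1.54 to 67.1 ± 3.34 FPKM, the EGFR ligand AREG from 57.3 ± 1.39 to 109 ± 5.89 FPKM and the AP-1 subunit FOSL1 from 53.3 ± 6.8 to 142 ± 6.1 FPKM. Immediate early genes had 12 higher and 3 lower members of 18 (camera adjusted p = 0.00064; adjusted p = 0.173 with an estimated correlation), and KLF6 rose 1.96-fold. This list shares 3 genes with the YAP list and 3 with the ERK list, so the counts are not independent.

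Ribosome biogenesis and MYC target genes also rose together. Of 35 measured, 33 were higher and 0 lower, with a median log2 fold change of 0.52 (camera adjusted p = 1.03e-17; adjusted p = 0.173 with an estimated correlation). MYC itself rose from 31 ± 1.11 to 50.4 ± 1.61 FPKM, and the ribosome assembly factors RRS1 and BOP1 rose 1.8-fold and 1.71-fold. DKC1, the pseudouridine synthase of small nucleolar particles, rose 1.52-fold. The cytosolic ribosomal protein genes themselves were not called as a list, with 1 of 76 higher and 12 lower (camera adjusted p = 0.202), except without NC replicate 3 (0.033) and without sh-RAD51C replicate 1 (0.000334), in a range up to 0.984. RPL13A and RPL3 fell by 0.33 and 0.22 on the log2 scale. Replication-dependent histones had 7 higher and 1 lower of 10 measured (camera adjusted p = 0.018; adjusted p = 0.382 with an estimated correlation), H2BC12 rising 1.65-fold. Histone copies are close paralogs, and the call was lost without the filter on low values (camera adjusted p = 0.139) and with voom on inferred reads (0.0565), in a range from 0.00502 to 0.382 over 19 alternatives with camera.

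Mesenchymal transition genes were mostly higher, 17 of 28 against 6 lower (median 0.36, camera adjusted p = 0.000491; adjusted p = 0.374 with an estimated correlation). The receptor kinase AXL rose from 29 ± 1.34 to 69.4 ± 5.15 FPKM, TGFB2 from 7.79 ± 0.256 to 18 ± 0.966 FPKM and the protease gene PLAU from 104 ± 0.494 to 195 ± 6.38 FPKM. WNT pathway targets had 8 higher and 2 lower of 13 (camera adjusted p = 0.00196, or 0.411 with an estimated correlation), led by CCND1, SOX9, DKK1 and MYC. AXL and TGFB2 are also on the YAP list. The mesenchymal list shares 3 genes with the YAP list, 2 with the WNT list and 1 each with the basal and glycolysis lists. The WNT list shares 1 gene each with the immediate early, ERK, ribosome biogenesis and basal lists. The counts of these lists are therefore not independent. TGF-beta targets went both ways, 10 higher and 8 lower of 27, and were not called (camera adjusted p = 0.344), except without genes with exon overlap (0.0292), in a range up to 0.556. TGFBR2 rose 2.2-fold and BHLHE40 was 1.63-fold lower.

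Basal and squamous urothelial markers were mostly lower. Of 29 measured, 23 were lower and 6 higher, with a median log2 fold change of -0.95 (camera adjusted p = 7.63e-08; adjusted p = 0.173 with an estimated correlation). KRT5, the basal keratin, fell from 686 ± 6.81 to 301 ± 3.04 FPKM, and the hemidesmosome collagen COL17A1 from 57.6 ± 1.99 to 24.6 ± 1.39 FPKM. Luminal urothelial markers were not called as a list, with 6 of 17 higher and 8 lower (camera adjusted p = 0.414). The simple-epithelium keratins KRT7 and KRT18 rose 1.68-fold and 1.63-fold, while the transcription factor KLF5 was 2.06-fold lower. Epithelial junction genes had 10 higher and 14 lower of 32 (camera adjusted p = 0.403). The desmosome genes PKP1 and DSC3 were 5.5-fold and 2.73-fold lower, and JUP was 1.46-fold lower.

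Cholesterol synthesis genes fell almost as a whole. Of 25 measured, 23 were lower and 0 higher, with a median log2 fold change of -0.47 (camera adjusted p = 4.85e-10; adjusted p = 0.173 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 22.2 ± 0.647 to 11.7 ± 0.999 FPKM, SQLE from 39.8 ± 1.07 to 23.4 ± 1.19 FPKM and FDFT1 from 64 ± 2.51 to 41.4 ± 1.08 FPKM. SREBF2, which encodes the main transcription factor of the pathway, was 1.62-fold lower. Fatty acid synthesis genes had 9 lower and 4 higher of 21 and were not called (camera adjusted p = 0.0671). Without NC replicate 1 (camera adjusted p = 0.0393), at a mean of at least 5 FPKM (0.0195), and without length and GC trends (0.0457) that list was called lower, in a range up to 0.482. The desaturases SCD and FADS2 were 2.18-fold and 1.76-fold lower. Glycolysis and hypoxia genes had 17 lower and 4 higher of 34 (camera adjusted p = 0.0189; adjusted p = 0.591 with an estimated correlation), with NDRG1 falling from 124 ± 11.3 to 37.4 ± 0.948 FPKM and EGLN3 2.39-fold lower. That call was lost without sh-RAD51C replicate 3 (camera adjusted p = 0.0784) and without genes with exon overlap (0.124), in a range from 0.00691 to 0.591.

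Inflammatory genes were divided. NF-kB and inflammatory cytokine genes had 23 lower and 7 higher of 35 (median -0.29, camera adjusted p = 0.00559; adjusted p = 0.516 with an estimated correlation). SOD2 fell from 74.1 ± 5.02 to 33.2 ± 1.3 FPKM and the RNase gene ZC3H12A was 1.95-fold lower, whereas the cytokine genes IL6 and IL11 rose, IL11 from 5 ± 0.279 to 17.9 ± 0.648 FPKM. Interferon-stimulated genes had 14 lower and 2 higher of 29 (camera adjusted p = 0.00293; adjusted p = 0.196 with an estimated correlation). IFI44 fell from 4.79 ± 0.38 to 2.17 ± 0.127 FPKM, and STAT2 and CXCL10 were 1.5-fold and 4.32-fold lower. Antigen presentation genes had 9 lower and 1 higher of 17 (camera adjusted p = 0.0189; adjusted p = 0.411 with an estimated correlation). TAPBP and TAP1 fell by 0.44 and 0.33 on the log2 scale and TAP2 rose by 0.29; the list was not called without genes with exon overlap (camera adjusted p = 0.101, in a range from 0.00377 to 0.411).

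The cell cycle lists, neither of which holds CCND1, moved little in their medians (0.04 for DNA replication and S phase). The G2 and mitosis list had 18 lower and 3 higher of 43, with a median log2 fold change of -0.07 (camera adjusted p = 0.0132; adjusted p = 0.556 with an estimated correlation). The phosphatase CDC25B fell from 118 ± 1.11 to 61.2 ± 0.806 FPKM, and TOP2A and KIF20A were 1.26-fold and 1.25-fold lower. Genes of DNA replication and S phase had 13 higher and 6 lower of 43 and were not called (camera adjusted p = 0.091) except without the filter on low values (0.0138), in a range up to 0.37, with cyclin E1 (CCNE1) 1.42-fold and CDC6 1.31-fold higher. Among apoptosis regulators 6 of 32 were higher and 13 lower (camera adjusted p = 0.414). The BH3-only genes BMF and BBC3 were 2.5-fold and 3.09-fold lower and CYCS was 1.4-fold higher.

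The remaining lists were not called by camera in the comparison of all 6 libraries. ATF4 targets had 10 higher and 5 lower of 28 (adjusted p = 0.249), STC2 rising 2.52-fold and DDIT4 falling from 353 ± 20.2 to 168 ± 4.78 FPKM. Matrix proteases and inhibitors had 9 higher and 15 lower of 28 (camera adjusted p = 0.283), with SERPINB2 2.05-fold higher and PLAT 2.29-fold lower. NRF2 targets had 8 higher and 5 lower of 25 (camera adjusted p = 0.792); AKR1C3 was 2.17-fold lower, TXNRD1 was 1.42-fold higher, and the list's median (0.01) and mean (-0.06) differed in sign. Lysosome and autophagy genes had 9 higher and 8 lower of 37 (camera adjusted p = 0.89), with a median of 0.05 and a mean of -0.03, and CTSD fell 1.75-fold. The unfolded protein response list had 2 higher and 5 lower of 23 (camera adjusted p = 0.792), XBP1 being 1.31-fold lower. Nuclear-encoded respiratory chain genes had 3 higher and 14 lower of 72 (camera adjusted p = 0.414), and were called lower with quantile normalization (0.0263) and without sh-RAD51C replicate 1 (0.0079), in a range up to 0.936. Mitochondrially encoded genes had 1 higher (ND2) and 1 lower (ND5) of 13 (camera adjusted p = 0.94). For the Fanconi anaemia list too the median (0.03) and mean (-0.02) differed in sign, and camera pointed up for the mitochondrially encoded genes at a median of -0.01.

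Markers of other cell types were mostly near 0. None of 11 endothelial markers averaged 1 FPKM, and 3 of 12 fibroblast and 3 of 11 blood cell markers did. Of these FBLN1, COL1A1, CD14 and LAPTM5 were lower in sh-RAD51C, with LAPTM5 at 97.7 ± 4.09 and 89.5 ± 2.01 FPKM, and THY1 and CD68 were higher. The calls of LAPTM5 and CD68 were lost in some alternatives, including the omission of single libraries (limma adjusted p up to 0.0994 and 0.103). The fibroblast gene COL1A2 and the leukocyte gene PTPRC were at or near 0 FPKM in all 6 libraries.

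**Figure D4:**
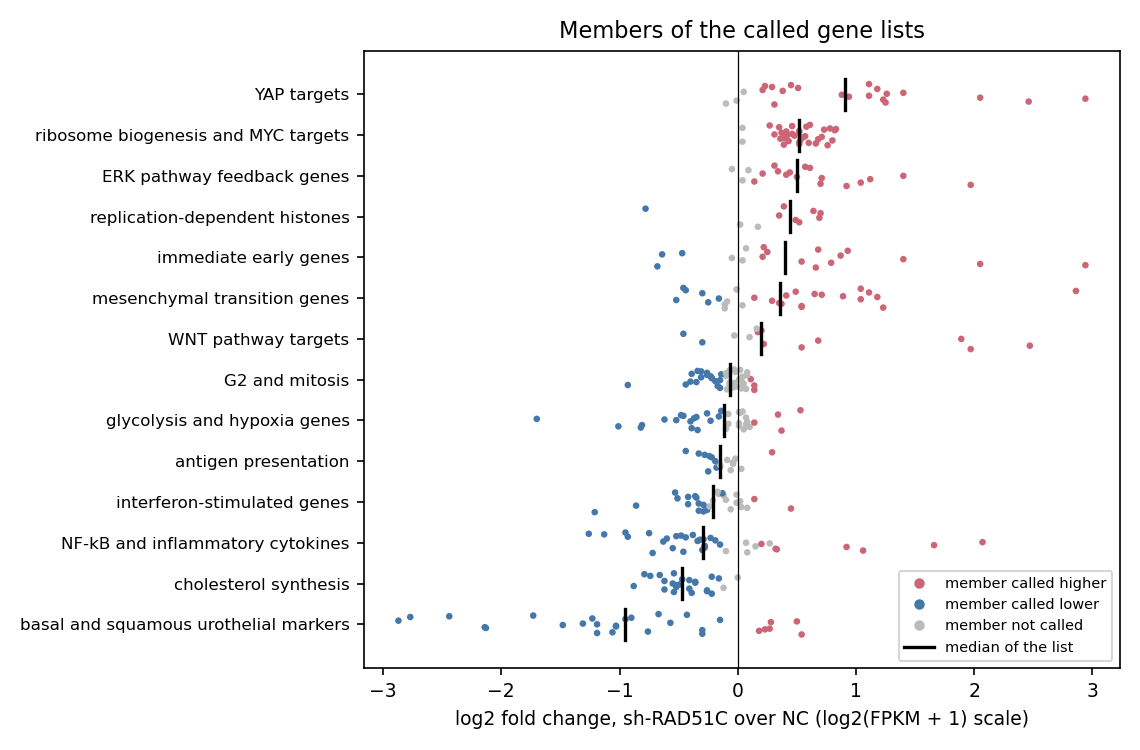
Log2 fold change of sh-RAD51C over NC for the measured members of the 14 called gene lists. Points are genes, coloured by call, and the black bar is the median of the list, which runs from 0.91 for YAP targets to -0.95 for basal and squamous markers.

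Camera called 14 of 32 lists at the preset correlation, 7 up and 7 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.173. The estimates for the called lists ran from -0.023 for immediate early genes to 0.37 for YAP targets. Immediate early genes lost their call (camera adjusted p from 0.00064 to 0.173) at an estimate below the preset 0.01. Correlation between genes therefore does not account for every lost call. With estimated correlations 6 lists had an unadjusted camera p under 0.05, and fry, which does not compare a list with other genes, called 24. The 10 lists called by fry and not by camera were ATF4 targets (fry adjusted p = 0.000154), S phase (0.000176), fatty acid synthesis (0.000502), TGF-beta targets (0.00162), luminal markers (0.00162), epithelial junctions (0.00546), apoptosis regulators (0.00939), p53 targets (0.0139), the unfolded protein response (0.025) and matrix proteases (0.0339). Adjusted over the list alone, the counts were the same for 10 of the 14 called lists; cholesterol synthesis then had 24 lower, interferon-stimulated genes 15, G2 and mitosis 19 and antigen presentation 10. Among lists not called the count changed most for cytosolic ribosomal proteins (1 higher and 4 lower) and respiratory chain genes (0 higher and 5 lower). The 3 sh-RAD51C libraries did not lie equally close to each other, with sh-RAD51C 1 at 9 on the second principal component (6.7% of the variance) and the others at -3.8 and -4.7. On that component NC 1 was at 3.4, and NC 2 and NC 3 were at -0.8 and -3.1. The first component (82.9%) separated the groups.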

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

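The alternatives that left out overlapping genes, removed length and GC trends or used voom were chosen after seeing the data. RAD51C was lower and called by limma under each alternative run on it, with log2 fold changes from -2.12 with voom to -1.2 with a pseudocount of 5, and from -1.88 to -1.78 when single libraries were left out. The number of genes called stayed within 1.5 times of 5511 except at a log2 fold change of at least 1, where 174 remained, 63 higher and 111 lower, and without single libraries it ran from 4513 to 5485. At a mean of at least 5 FPKM 7376 genes were tested. Genes called lower then numbered 1859 against 2922, and genes called higher 2088 against 2589. Of the calls 52.9% were higher, against 47% in the main fit. The balance of directions therefore depended on the expression level of the genes tested. Camera called 13 to 16 lists in the fits without single libraries, 0 lists with an estimated correlation and 24 by fry, which also asks another question. Deviations from the group mean correlated at 0.19, 0.026 and 0.091 between libraries of the same number, for numbers 1, 2 and 3. Across the groups, libraries of different numbers correlated at -0.167 to 0.11, so the pair numbered 1 was the closest. A component shared by the libraries numbered 1 is therefore not excluded. A replicate block gave 5569 genes. Among 2828 values of named genes under alternatives, 2787 kept direction and call, 21 lost the call, 17 gained it and 3 reversed. Of 701 list values, 645 kept both, 19 lost the call, 19 gained it and 18 reversed.

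All reversals were of genes or lists not called in either fit, and their cause was not tested. IGF2-AS was at 0.03 with quantile normalization and ran from -0.16 to 0 without single libraries, turning without NC replicate 3, and RAD51D ran from 0 to 0.04, turning without sh-RAD51C replicate 1. List medians where the direction by camera or fry turned were as follows. The Fanconi anaemia list was at 0.03 without a filter and without sh-RAD51C replicate 1 (range without single libraries -0.01 to 0.05), at 0.07 with quantile normalization and at 0.05 without overlapping genes. The lysosome list was at 0.04 at a mean of at least 5 FPKM, at 0.02 with quantile normalization and without overlapping genes, at 0.03 without sh-RAD51C replicate 1 (range 0.03 to 0.06) and at 0.05 by fry. Mitochondrially encoded genes were at -0.01 at a mean of at least 5 FPKM, with voom and by fry, and turned without NC replicate 3 (-0.03) and sh-RAD51C replicate 1 (-0.04; range -0.04 to 0.07). At a mean of at least 5 FPKM homologous recombination was at 0.01 and end joining at 0.03. The respiratory chain list was at -0.01 without sh-RAD51C replicate 3 (range -0.08 to -0.01) and NRF2 targets at 0.01 by fry.

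The rescalings moved the median of all genes from -0.011 to between -0.019 and 0.01, and the share of called genes that were higher from 47% to between 45% and 51.6%. With 3 simulated libraries per group at the inferred depth, 14% of 1.1-fold changes and 68% of 1.2-fold changes were recovered. Depth itself was not varied. Few genes were changed there, against 49.4% called in the data, and all had 1 common spread. These percentages therefore do not give the share of real changes that this comparison would recover.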

Other observations

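Genes of the mitochondrial ribosome, TIMM genes of protein import into mitochondria and PSMD genes of the proteasome were also higher in the sh-RAD51C libraries at camera's preset correlation, though not with an estimated one (adjusted p from 0.958 to 0.973). The tests of symbol families, depth, growth state, copy loss, partner abundance of antisense genes, their spread within NC and the difference of medians between strands were chosen only after the results were seen, as were the removal of length and GC trends and the condition that set the strand comparison aside. The chromosome 11 run was noticed while gene values were read, its window of 10 genes was set after that, and the genes and noncoding classes named here were chosen after their values were seen. Genes were grouped by the root of their symbol, and 101 roots with at least 12 tested genes were compared by limma's camera. Of 51 MRPL genes, which encode the large mitochondrial ribosomal subunit, 34 were higher and 1 lower, with a median log2 fold change of 0.17 (camera adjusted p = 1.67e-05; adjusted p = 0.958 with an estimated correlation). Of 28 MRPS genes, 16 were higher and 0 lower, and of 15 TIMM genes of inner membrane import, 12 were higher and 1 lower (adjusted p = 0.973 and 0.958 with an estimated correlation). Of 14 PSMD genes, which encode proteasome regulatory subunits, 10 were higher and 0 lower (median 0.17, camera adjusted p = 0.0062; adjusted p = 0.958 with an estimated correlation), while PSMB8, PSMB9 and PSMB10 of the proteasome were lower, at -0.24, -0.28 and -0.22. POLR (RNA polymerase subunits), DUSP (dual-specificity phosphatases), EIF (translation initiation factors), DDX (RNA helicases) and SNHG genes were higher as roots as well (camera adjusted p from 0.662 to 0.958 with an estimated correlation). The ERK feedback and immediate early lists also hold DUSP genes, and the ribosome biogenesis list holds POLR and DDX genes. The calls of these roots are therefore not independent of those lists. KDM genes, many of them histone demethylases, had 9 lower and 1 higher of 16 (median -0.24), and ARHGEF genes 13 lower and 3 higher of 23 (adjusted p = 0.973 for both with an estimated correlation). The medians of these 11 roots kept their sign under each rescaling.

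Neighbouring genes at the H19 and IGF2 region of chromosome 11 were lower together. Between 1732410 and 2149603 (GRCh38), 10 genes were tested and 8 were called lower, IFITM10 (3.13-fold), CTSD (1.75-fold), SYT8 (2.32-fold), TNNI2 (3.44-fold), LSP1 (5.76-fold), TNNT3 (5.93-fold), H19 (7.13-fold) and IGF2 (1.84-fold), while MRPL23, between TNNT3 and H19, and IGF2-AS were not. Their median log2 fold change was -0.94, the lowest of 10763 windows of 10 genes together with the window that begins 1 gene earlier. Among 1000 permutations of gene order 0 gave a window as low (share 0.001, the smallest they can give), but the window was set after the run was noticed and shuffling also removes the clustering of related genes, so random positions stay open. The next lowest separate windows held gene families, S100 and SPRR genes on chromosome 1 (-0.88) and type I keratins on chromosome 17 (-0.84). Uniform loss of copies of the region is argued against by MRPL23, at 13.3 ± 0.281 FPKM in NC and 12.4 ± 0.916 in sh-RAD51C (log2 fold change -0.1, SE 0.054). What lowered these genes together, and whether it follows from RAD51C loss or from a difference between the cell populations, was not tested.

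The window with the largest median rise (0.47) lay on chromosome 8 and held MYC and its neighbours CASC19, CASC8 and PVT1. In NC and sh-RAD51C, CASC19 was at 0.977 ± 0.342 and 3.43 ± 0.31 FPKM and PVT1 at 5.02 ± 0.245 and 8.16 ± 0.815 FPKM (SD, n = 3 each). Of 75 LINC-named genes 28 were lower and 10 higher, and of 51 divergent transcripts 14 were lower and 4 higher (median log2 fold changes -0.13 and -0.1). Over all genes tested 26.2% were called lower and 23.2% higher. The divergent transcripts called lower were near the general share, while those called higher were below it. LINC-named genes lay above the share for lower calls and below it for higher calls. Neither class was compared with genes of a like expression level. SNHG genes had 12 higher and 0 lower of 23. No test was run on the LINC-named genes and divergent transcripts.

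Of the 11152 genes tested 49.4% were called, and some technical causes that would spread over many genes were tested. A difference in culture or library preparation that coincides with the groups was not tested and cannot be told apart from the knockdown. Since the hairpin sequence is not given, effects of the hairpin other than on RAD51C cannot be told apart from RAD51C loss either. The groups differed little in depth (ratio of mean totals 1.02). Removing each library's trend with length and GC content left 5826 genes called, 4981 of them called in the same direction as before, and quantile normalization left 5554, of which 4961 were shared. These values argue against depth, length, GC content or a few abundant genes as the whole cause. Without the length and GC trends the 13 called lists that could be run stayed called in the same direction (the histone genes had no GC value), and with quantile normalization all 14 did. A lower density or faster growth of the knockdown cultures may still contribute and cannot be told apart from the knockdown. Either was taken to raise the G2 and mitosis list. That list was lower at the preset correlation (18 lower and 3 higher of 43, camera adjusted p = 0.0132). It was not called with an estimated correlation (camera adjusted p = 0.556), a setting that called 0 of 32 lists and so could hardly decide. S phase genes leaned the other way (13 higher and 6 lower of 43, not called).

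There are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 5511 genes (2589 higher and 2922 lower), 1 of 10 with as many, and the highest of the other splits gave 0 at an adjusted p under 0.05 by limma (at most 267 genes at an unadjusted p under 0.05). For lists the real split called 14 and the highest other 13, and the other splits called at least 8. Each of the other splits keeps part of the difference between the groups, since 2 of 3 libraries on a side share a group. For genes, the group difference (first component, 82.9% of the variance) also widens the spread within each side of such a split. A count of 0 there was therefore largely fixed beforehand, and the contrast with 5511 lends the group labels no support.

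Antisense-named genes were lower more often than higher in the knockdown libraries, 72 against 18 of 160, with a median log2 fold change of -0.2. Across 155 antisense genes the change was more negative where the sense partner was more abundant relative to the gene (Spearman rho -0.31, permutation p = 0.00012; genes are not independent replicates), which is consistent with reads of the partner entering the value, but 85 genes with a partner under 5 times their own level also had a median of -0.13, against -0.011 over all genes, so partner reads may account for only part of the shift. The antisense genes were not compared with other genes of a like expression level. For the 29 genes with a partner at least 20 times as abundant, NC 1 lay above the other NC libraries by a median of 0.38. In the same genes sh-RAD51C 1 lay above the other sh-RAD51C libraries by a median of 0.3, which was not tested. For NC 1 the sign test did not pass (20 of 29 higher, exact sign test p = 0.061), so a difference within NC is not established. This test does not decide, and an effect of the knockdown alone still cannot be told apart from library preparation. For incomplete strand marking, the NC 1 shift of 8 genes overlapped on the same strand was -4.58 times that of 111 genes overlapped on the opposite strand, on the side predicted beforehand if marking were the cause. That ratio was set aside once seen, because the opposite-strand shift it divides by was only 0.04; the medians differed (-0.19 against 0.04, permutation p = 0.028), but through the same-strand genes, which this explanation leaves in place, so it cannot be told apart either.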
